A study of Homo sapiens with 24 samples.

How the data were processed

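RNA sequencing of 24 libraries from the cutaneous T cell lymphoma lines MyLa and HuT 78 was analysed through the 2 comparison tables that the authors made from it. Per the labels, 8 groups of 3 libraries combine the line, the hairpin (non-targeting control, NTC, or shPRKCQ) and the treatment (DMSO or TPA). For the knockdown, cells were kept in 1 µg/ml doxycycline for at least 72 h before a treatment of 24 h with vehicle or with 10 ng/ml TPA, per the labels' protocols. The protocols do not say whether NTC cells also received doxycycline; if they did not, effects of the drug and of the hairpin cannot be separated in either comparison. Libraries were strand-specific, made from poly(A)-selected RNA, and carried unique molecular identifiers, per the labels' protocols. The submitters' processing notes list STAR 2.5.3a, RSEM 1.3.0, DESeq2 1.18.1 and the build GRCh38, without saying which step each served. The model formula, the covariates, the use of the molecular identifiers and any shrinkage of fold changes are not given in the sources used here.

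Each table sets NTC against shPRKCQ libraries of both lines together, 6 against 6 libraries, for 1 treatment. Per the file headers, the deposited columns are a log2 fold change, a p-value and an adjusted p-value per gene. Adjusted p-values were checked against a Benjamini-Hochberg adjustment of the p-values and differed from it by a relative 0.00235 at most in DMSO and 0.00451 in TPA. The tables do not state the direction of the fold change, so a negative value was taken as lower in shPRKCQ cells, because PRKCQ itself is negative in both. The DMSO table lists 13025 genes, of which 13007 have a p-value. The TPA table lists 58780 genes, of which 34024 have a p-value and 19417 an adjusted p-value. All gene identifiers matched GENCODE release 29, whose symbols and GRCh38 coordinates are used; the symbols in the tables differed for 11 and 16 genes, including 3 and 14 shown as numbers. Fold changes of the TPA table appear to be shrunken by the authors: of 34085 genes with a fold change, 2912 share the value 0.000537. None of the DMSO values is shared by more than 3 genes, but that table lists fewer genes, so such ties could be missing from it. Implied standard errors were compared over genes whose z was not small in either table. Their median ratio in TPA over DMSO was 0.749 among genes above 0.4 in DMSO and 0.978 among genes at or under 0.1. Grouping by the DMSO value can by itself lower the ratio in the highest group. Fold changes may therefore not be on 1 scale across the tables, which these values cannot settle.

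No value per library was used, so sequencing depth is unknown, the PRKCQ level of each library is not analysed here, and no count test was run. The design fixed before the data were examined asked for edgeR fits on counts and, failing that, for a description of the authors' own values, which is what is given. For tables of this kind the design left the interaction of knockdown and TPA untested; the difference tests below were added after the form of the tables was seen. The list tests were planned, and their use of z-values in place of library values was set at that point. Comparisons within 1 line, between the lines and between TPA and DMSO in the same cells are not analysed here for the same reason. A gene was called at an adjusted p under 0.05 in the authors' column. The labels call the replicates independent, and the tables give the authors' p-values without the spread between libraries.

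From each table a z-value was computed per gene from the p-value and the sign of the fold change, and an implied standard error as the fold change divided by z. The 31 gene lists fixed before the data were examined were tested with cameraPR of limma 3.58.1 (R 4.3.3) on the z-values, with a preset correlation of 0.01 between genes, two-sided, over lists with at least 3 genes, with Benjamini-Hochberg adjustment over the lists of a table. This replaces camera on library values; an estimated correlation and fry need library values and were not run. The list p-values therefore measure agreement between genes and not the spread between libraries. Members were also tested with the adjustment made over the list alone. The knockdown effects in DMSO and TPA were compared by the difference of fold changes over the implied standard errors, taking the tables as independent; they share no library, but both treatments could use the same cultures. Overlap of calls was set against the count that independent lists would give, again taking the tables as independent. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

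For the list tests, z-values were simulated for the same genes and lists, independently for each gene. A list shifted by 1 was recovered in 96% of 100 runs for DMSO and 94% for TPA. Of unshifted lists, 3.76% and 2.71% had an unadjusted p under 0.05. Correlation between the genes of a list was not simulated, so these rates do not cover lists whose genes vary together. The difference test recovered 99.6% of genes shifted by 6 standard errors, with 4.99% false among its calls. The rescaling of p-values recovered 94.3% of genes shifted by 5, with 3.87% false. Rescaling divides all z-values by 1 robust SD and so takes unchanged genes to share 1 spread. Whether they do is not known from the values used here.

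Genes are named by a rule fixed before the data were examined: PRKCQ, the 6 largest rises and 6 largest falls among called genes, leaving out clone-based symbols and pseudogenes, and up to 2 called members per list. A gene that the rule names is not reported here, though counts include it. The rule also asked for a minimum mean expression and the same sign in each line, and for the highest-expressed members of lists without a called gene; these could not be applied without library values. For lists without a called gene, members are named by the smallest unadjusted p or by passing over the list alone, and for some lists none is named; this departure was made after the values were seen. EAF1, FNIP2, AC008012.1, CIITA, HLA-DQA1, FGFR1 and other genes outside the rule were likewise chosen after their values were seen. Alternatives planned beforehand were a minimum fold change, a stricter threshold for the overlap and an adjustment without a filter on low genes. Those added after the data were seen were rescaled p-values, ranks, a preset correlation of 0.05, other sets of genes for the adjustment, and a difference on the scale of z-values.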

Results

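PRKCQ encodes protein kinase C theta, a protein kinase C that couples the T cell receptor to NF-kappaB, AP-1 and NFAT. Its knockdown was examined by RNA sequencing in MyLa, a line from mycosis fungoides, and HuT 78, a line from Sézary syndrome. The libraries were 24 in number, 3 for each combination of line, hairpin and treatment. TPA is a phorbol ester that activates protein kinase C directly, and DMSO is its vehicle. Each comparison set 6 shPRKCQ libraries against 6 NTC libraries over both lines. Each value combines MyLa and HuT 78, with weights that are not known here, and does not show whether the lines differ. Depth per library is unknown here.

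The first question was how far PRKCQ itself was lowered. PRKCQ (ENSG00000065675.14, chromosome 10, 6427143 to 6580301, minus strand, GRCh38) had a log2 fold change of -2.11 in DMSO in the authors' deposited table, which is 23.1% of the NTC level (adjusted p = 5.61e-14). In TPA the authors' deposited table gave -2.08, or 23.7% of the NTC level (adjusted p = 1.67e-15). It had the smallest adjusted p of all genes in both treatments. The transcripts of the other protein kinase C and D family genes gave no call: 10 were tested in DMSO and 12 in TPA, with list medians of -0.030 and 0.0063 (cameraPR adjusted p = 0.593 and 0.998). PRKCA, a classical protein kinase C, was at -0.26 in DMSO and -0.20 in TPA in the authors' deposited tables, with unadjusted p = 0.162 and 0.274.

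In vehicle-treated cells 14 of 13007 genes passed, 4 higher and 10 lower in shPRKCQ cells; p-values rescaled for their narrow spread gave 108, 40 higher and 68 lower. Among the genes that fell were members of the NFAT and Notch lists. NFATC2, the calcineurin-controlled transcription factor NFAT1, was at -0.65 and NOTCH1, a receptor with oncogenic roles in T cells, at -0.40 on the log2 scale in the authors' deposited table (adjusted p = 0.00422 and 0.0483). LIMK1, a kinase that phosphorylates cofilin and so slows actin turnover, fell by 0.61 in the authors' deposited table (adjusted p = 0.00422). Larger falls were those of LDLRAD3, a membrane receptor of the low-density lipoprotein receptor family, at -1.29, MROH6 at -0.76 and RBM47, an RNA-binding protein, at -0.71 in the authors' deposited table. Among the 4 genes that rose, the authors' deposited table has TMEM136 at 0.73 and MRFAP1 at 0.52. RN7SK, the small nuclear RNA that holds the elongation factor P-TEFb inactive, was at 4.20 in the authors' deposited table (adjusted p = 0.0149); it is an RNA polymerase III transcript without a poly(A) tail, with many near-identical copies in the genome, and 6 further non-polyadenylated RNAs were positive beside it. The remaining calls, outside the naming rule, were EAF1 at -0.38, FNIP2 at -0.35 and the clone-based gene AC008012.1 at -0.84 in the authors' deposited table; the last overlaps CCND2 and TIGAR on the same strand. The calls of NOTCH1, MROH6 and FNIP2 were lost when non-polyadenylated and histone genes were left out of the adjustment (adjusted p = 0.0519 for each). With a minimum absolute log2 fold change of 1, 3 of the 14 genes were left.

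Under TPA the knockdown changed 22 of 19417 genes, 5 higher and 17 lower; rescaled p-values gave 114, 42 higher and 72 lower. The deepest fall was that of NLRP2, a NOD-like receptor of innate immunity, with a log2 fold change of -2.42 in the authors' deposited table (adjusted p = 9.85e-07). After PRKCQ, the next falls in the authors' deposited table were those of ATAD3C at -1.84, SEZ6L at -1.81, NUAK1, an AMPK-related kinase, at -1.64 and SUCNR1, the succinate receptor, at -1.60. ATAD3C has close paralogs in ATAD3A and ATAD3B, so its reads could be split between them. Genes that rose in the authors' deposited table included SPP1, the secreted cytokine osteopontin, at 1.52 and TFCP2L1 at 0.55. SPINK5, a serine protease inhibitor of skin, and CPM, a carboxypeptidase, rose to 2.84 and 2.26 times the NTC level, computed from the authors' deposited table. Of the 22 genes, 12 are not in the DMSO table, among them NLRP2, SPP1, SPINK5, ATAD3C and SEZ6L, so they could not be compared with vehicle. An adjustment without the filter on low genes gave 20 calls and kept 17 of the 22; SPP1 and SEZ6L were among those lost. With a minimum absolute log2 fold change of 1, 14 genes were left.

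**Figure D1:**
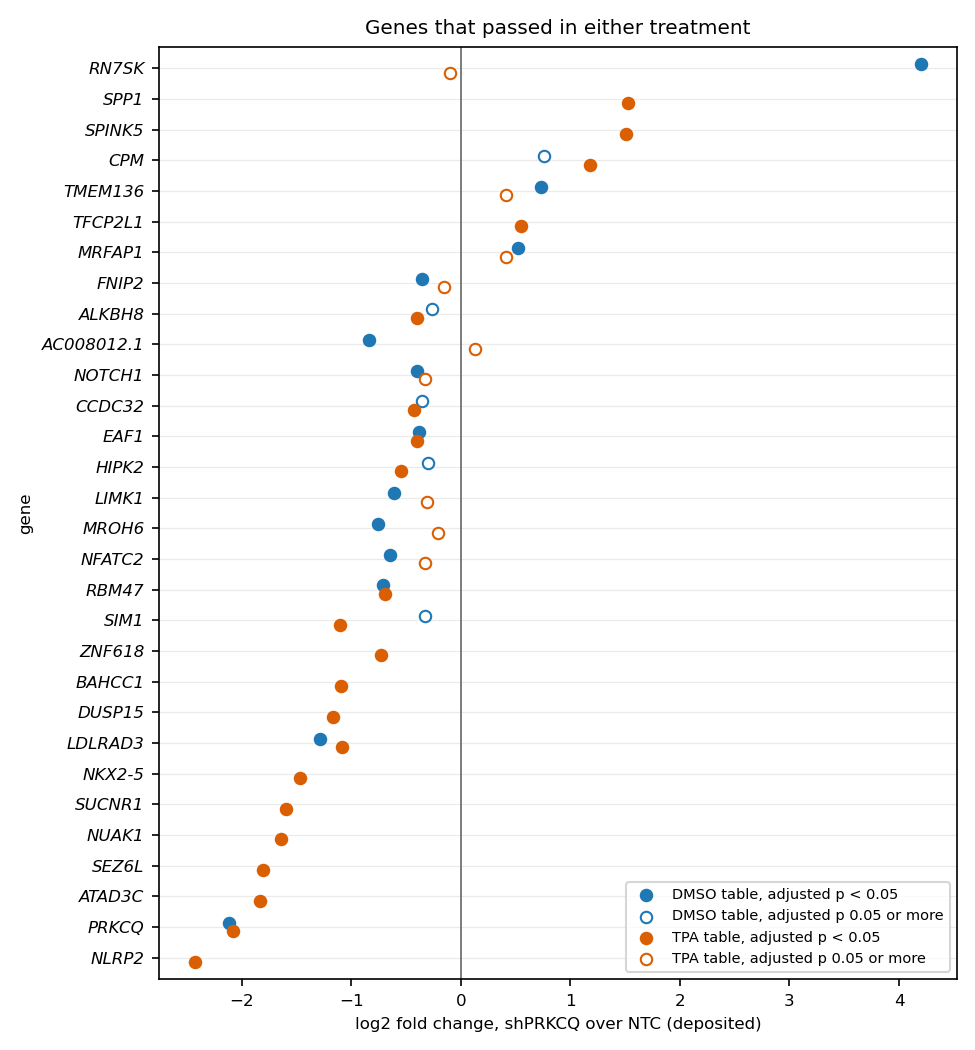
Log2 fold change of shPRKCQ over NTC (x axis) in DMSO (blue) and TPA (orange) for each gene reported here that was called in either of the authors' deposited tables (y axis); filled points passed an adjusted p of 0.05 and a gene without a point in a colour has no adjusted p in that table. PRKCQ lies at -2.11 and -2.08, and RN7SK at 4.20 in DMSO against -0.10 in TPA.

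A small set of genes moved the same way with and without the phorbol ester. EAF1, a partner of the ELL elongation factors, LDLRAD3, PRKCQ and RBM47 fell in both treatments. In all, 5 calls were shared, PRKCQ itself among them, where independent lists would give 0.0108 among 13007 genes. The tables share no library, but cultures of both treatments could be related, so this chance value may be too low. The same 5 genes passed in both at an adjusted p under 0.01. The sizes of the falls were alike: in the authors' deposited tables EAF1 was at -0.38 and -0.40, LDLRAD3 at -1.29 and -1.08 and RBM47 at -0.71 and -0.69 in DMSO and TPA. At an unadjusted p under 0.05, 133 genes were shared where 13.3 would be by independence, and all 133 had the same sign, 90 lower and 43 higher. Across the genes of both tables without PRKCQ, which are not independent replicates, the z-values of the treatments had a Pearson r of 0.516 and a Spearman rho of 0.458. By the difference test, 0 of 13007 genes had a knockdown effect that passed as different between TPA and DMSO, with 57 at an unadjusted p under 0.05. That test looks conservative over all genes, with a robust SD of 0.587 for its z-values, and rescaled p-values gave 18 genes. Of the genes called in either table, RN7SK and AC008012.1 are the only ones among the 18 (rescaled adjusted p = 6.48e-08 and 7.61e-08). In the authors' deposited tables RN7SK was at 4.20 in DMSO and -0.10 in TPA, and AC008012.1 at -0.84 and 0.13. NFATC2 was at -0.65 in DMSO and -0.33 in TPA, and NOTCH1 at -0.40 and -0.33, in the authors' deposited tables. Neither is among the 18 (rescaled adjusted p = 0.363 and 0.995), so their calls in DMSO alone are not shown to differ from TPA.

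Among the fixed gene lists, interferon-stimulated genes rose as a group in DMSO. Of 19 members 15 were positive, with a median log2 fold change of 0.34 (cameraPR adjusted p = 8.22e-08 over 29 lists). No member passed over all genes, and 5 passed when adjusted over the list alone: IFIT2 at 1.29, IFIT1 at 1.25, IFIT3 at 1.08, ISG15 at 0.77 and IFI44 at 0.98 in the authors' deposited table. These are antiviral effectors and, for ISG15, a ubiquitin-like modifier. In TPA 19 of 25 members were positive with a median of 0.16, which did not pass (adjusted p = 0.0678). The other list that passed in DMSO was that of ATF4 and the unfolded protein response, which fell, with 17 of 20 members negative, a median of -0.20 and an adjusted p of 0.00171. None of its members passed alone; ASNS, asparagine synthetase, was at -0.44 and CRELD2 at -0.25 in the authors' deposited table. In TPA the list median was -0.015 (adjusted p = 0.333). Among the DMSO values, 6 non-polyadenylated RNAs besides RN7SK had a median of 1.78 and 21 histone genes a median of 0.42.

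In TPA, genes of MHC class II fell as a group: all 14 members were negative, with a median of -0.34 (cameraPR adjusted p = 1.97e-07 over 31 lists). RFX5, a promoter-binding factor of these genes, was at -0.24 and HLA-DRA at -0.86 in the authors' deposited table (unadjusted p = 0.0214 and 0.0273). CIITA, the master regulator of the class, was at -0.64 and HLA-DQA1 at -0.48 in the authors' deposited table, both chosen after their values were seen. No member passed over all genes or when adjusted over the list alone. In DMSO 10 members were tested, without HLA-DRA and HLA-DQA1, and the median was -0.053 (adjusted p = 0.476). Genes of DNA replication and S phase fell with all 24 members negative and a median of -0.24 (adjusted p = 6.76e-06). TYMS, thymidylate synthase, was at -0.42 and MCM5, a subunit of the replicative helicase, at -0.31 in the authors' deposited table. No gene of the S phase list passed over all genes or when adjusted over the list alone. Mitotic genes also fell, with 22 of 24 negative and a median of -0.15 (adjusted p = 0.0414). In DMSO 22 of the 24 mitotic genes were positive, with a median of 0.12 that did not pass (adjusted p = 0.2), and the S phase list had a median of -0.043 (adjusted p = 0.593). T cell receptor signalling genes rose in TPA, 23 of 29 positive with a median of 0.12, and cholesterol synthesis genes fell, 17 of 22 negative with a median of -0.071 (both adjusted p = 0.0492); both calls were lost when non-polyadenylated and histone genes were left out (adjusted p = 0.05 for each). LAT, the adaptor downstream of ZAP70, was at 0.36 and INSIG1 at -0.51 in the authors' deposited table, neither past the threshold. In DMSO the medians of these lists were 0.00089 and -0.088 (adjusted p = 0.809 and 0.2). An estimated correlation between genes could not be used. With a preset correlation of 0.05 the MHC class II and S phase lists passed in TPA and both DMSO lists passed, while the mitotic, T cell receptor and cholesterol lists did not (adjusted p = 0.304, 0.318 and 0.318).

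**Figure D2:**
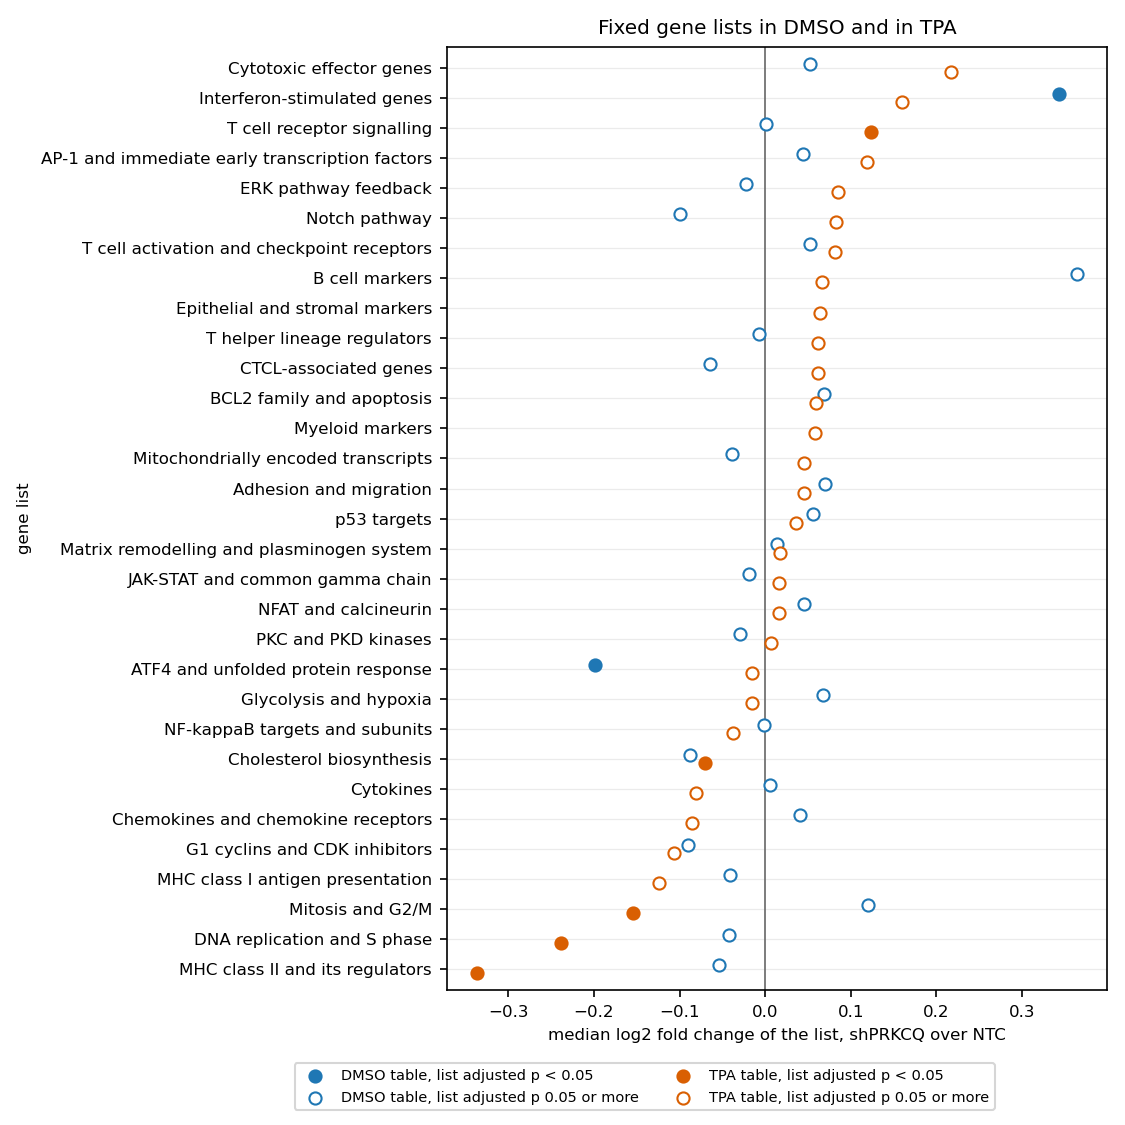
Median log2 fold change of shPRKCQ over NTC (x axis) of each fixed gene list with at least 3 genes tested (y axis), in DMSO (blue) and TPA (orange); filled points passed the list test at an adjusted p of 0.05. The MHC class II median lies at -0.34 in TPA, and that of interferon-stimulated genes at 0.34 in DMSO.

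After 24 h of treatment, the NF-kappaB, AP-1 and NFAT lists gave no list call with vehicle or TPA, nor did the ERK feedback, JAK-STAT and Notch lists. The NF-kappaB list had medians of -0.0014 in DMSO and -0.038 in TPA (adjusted p = 0.844 and 0.322). AP-1 and immediate early genes had medians of 0.044 and 0.12 (adjusted p = 0.767 and 0.118); JUN was at 0.66 and 0.62 in the authors' deposited tables, with an unadjusted p of 0.0105 in each. The NFAT and calcineurin list had medians of 0.045 and 0.016 (adjusted p = 0.2 and 0.334), and besides NFATC2 in DMSO its member CABIN1, a calcineurin inhibitor, passed when adjusted over the list alone, at -0.35 and -0.32 in the authors' deposited tables. ERK feedback genes had medians of -0.022 and 0.085 (adjusted p = 0.593 and 0.471) and JAK-STAT genes medians of -0.019 and 0.017 (adjusted p = 0.617 and 0.667). IL2RB, the shared chain of the interleukin-2 and interleukin-15 receptors, passed when adjusted over the list alone in DMSO, at -0.83 in the authors' deposited table. The Notch list had medians of -0.099 and 0.083 (adjusted p = 0.321 and 0.924); in TPA NOTCH1 passed when adjusted over the list alone.

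Effector and lineage lists also stayed short of the threshold. Cytokines had medians of 0.0056 and -0.081 in DMSO and TPA (adjusted p = 0.809 and 0.166), and 2 of the 28 tested in TPA passed when adjusted over the list alone: IL10 at -1.07 and IFNG at -1.59 in the authors' deposited table. Chemokines and their receptors had medians of 0.040 and -0.086 (adjusted p = 0.593 and 0.822). Activation and checkpoint receptors had medians of 0.052 and 0.082 (adjusted p = 0.564 and 0.322), with TNFRSF9, the costimulatory receptor 4-1BB, at 0.94 and CD6 at 1.02 in TPA in the authors' deposited table, both past the threshold over the list alone. Cytotoxic genes had medians of 0.053 and 0.22 (adjusted p = 0.756 and 0.147). T helper lineage regulators had medians of -0.0073 and 0.062 (adjusted p = 0.321 and 0.958); over the list alone SATB1, a chromatin organiser, passed in DMSO and EOMES in TPA, at -1.11 and -0.76 in the authors' deposited tables. The list of genes associated with cutaneous T cell lymphoma, which shares SATB1, had medians of -0.065 and 0.062 (adjusted p = 0.2 and 0.291).

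The remaining lists did not pass in either treatment. In DMSO and TPA their medians were -0.090 and -0.11 for G1 cyclins and their inhibitors (adjusted p = 0.422 and 0.128), 0.069 and 0.060 for the BCL2 family (0.476 and 0.658) and 0.056 and 0.036 for p53 targets (0.809 and 0.849). Adhesion and migration genes had 0.070 and 0.045 (adjusted p = 0.458 and 0.228), and matrix remodelling genes 0.013 and 0.018 (0.855 and 0.599). MHC class I genes had -0.041 and -0.12 (adjusted p = 0.593 and 0.147). Glycolysis and hypoxia genes had 0.068 and -0.016 (adjusted p = 0.232 and 0.924), and mitochondrially encoded transcripts -0.039 and 0.045 (0.232 and 0.333). Of markers of other cell types, B cell genes had 0.36 over 3 genes in DMSO and 0.066 over 7 in TPA (adjusted p = 0.593 and 0.924), where CD79B passed over the list alone at -1.10 in the authors' deposited table. Myeloid and epithelial or stromal markers had 2 genes each in DMSO, too few for the test, and medians of 0.059 and 0.064 in TPA (adjusted p = 0.914 and 0.924). For 4 lists in DMSO and 6 in TPA the median, the mean and the test did not share 1 sign; none of these passed.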

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

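The tests of differences between the treatments, of genes and of lists, were chosen only after the data were seen. Of the fixed gene lists, 7 passed for a difference in knockdown effect between TPA and DMSO when the gene-wise differences were tested with cameraPR. Of single genes 0 passed, with 57 at an unadjusted p under 0.05 and 18 with rescaled p-values. The 7 lists were picked out by that test of the difference. Its p-values rest on agreement between the genes of a list, not on the spread between libraries. A shift between cultures in genes that vary together could give them too. The fold changes are list medians over genes that both tables hold.

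Mitotic genes stood out most: 24 genes with a median of 0.12 in DMSO and -0.15 in TPA (adjusted p = 3.29e-05). DNA replication and S phase genes had medians of -0.043 and -0.24 (adjusted p = 0.000714). Interferon-stimulated genes had 0.34 in DMSO and 0.20 in TPA, where the list alone did not pass (adjusted p = 0.00277). MHC class II genes, 10 of them, had -0.053 and -0.29 (adjusted p = 0.00277). Mitochondrially encoded transcripts had -0.039 and 0.045 (adjusted p = 0.00277), a pair of values close to 0. Genes associated with cutaneous T cell lymphoma had -0.065 and 0.060 (adjusted p = 0.0387). The ATF4 and unfolded protein response list had -0.20 and -0.015 (adjusted p = 0.0395). With a preset correlation of 0.05, 5 of the 7 lists passed, without the last pair. On the difference of z-values 6 passed, without the ATF4 list.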

How the results depend on the processing

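Alternatives other than a minimum fold change, a stricter threshold for the overlap and an adjustment without a filter were chosen after seeing the data. No paired analysis was possible because the tables used here hold no value per library. Not run for the same reason were other normalizations and tools, stricter filters, left-out replicates, other splits of the libraries, an estimated correlation, fry and pseudocounts. Depth is unknown, so what it limits could not be assessed.

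PRKCQ passed under every alternative run. Over all genes the authors' p-values look conservative. The robust SD of z was 0.756 in DMSO and 0.838 in TPA. Of the p-values, 3.04% and 3.99% lie under 0.05 where chance gives 5%. The plain SD of z was larger, at 0.857 and 0.928. If unchanged genes do not share 1 spread, rescaling could give too many calls. Rescaled p-values gave 108 calls in DMSO (40 higher, 68 lower) and 114 in TPA (42 higher, 72 lower), with 16 shared. They gave 18 genes past the difference test, RN7SK among them, where the difference of z-values without rescaling gave 0. A minimum absolute log2 fold change of 1 left 3 calls in DMSO and 14 in TPA by its own construction. Adjusting TPA over the genes of the DMSO table left 8 calls; 12 of the 22 genes are not in it and 2 more were lost. TPA lists passing numbered 2 with a preset correlation of 0.05 and 3 without non-polyadenylated and histone genes, where 2 lists moved from 0.0492 to 0.05. The overlap of 5 genes was the same at an adjusted p under 0.01. Of 97 values for called genes other than PRKCQ, 87 stayed past the threshold and 10 did not. Of the 97, 34 come from rescaled p-values, which are smaller for every called gene and so could not lose a call. All alternatives used the same fold changes, so no sign could reverse. NOTCH1, FNIP2 and MROH6 were lost in DMSO without non-polyadenylated and histone genes. Their p-values are the same in both settings. Only the adjustment changed, because RN7SK, a called gene with a smaller p, was left out of it.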

Other observations

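Of the tests below, the combination of the tables, those of non-polyadenylated RNA, the shares of genes with a word and the correlation of adjacent genes were chosen only after the data were seen.

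The z-values of both tables were added, and the combined z was rescaled by its own robust SD of 0.931. This gave 142 genes at a combined adjusted p under 0.05, 46 higher and 96 lower in shPRKCQ cells, and 125 of them were called in neither table. The rescaling sets the spread over all genes, but differences between cultures shared by both treatments would still count in both tables. The genes with the smallest combined p among the 125 were HIPK1, a nuclear kinase, at 0.34 and 0.27 in DMSO and TPA, STX6, a syntaxin of the Golgi and endosomes, at 0.43 and 0.49, SFXN1, the mitochondrial serine transporter, at -0.41 and -0.48, and WDR82, a partner of the SET1 histone methyltransferases, at -0.18 and -0.20 in the authors' deposited tables. Chosen after its values were seen, the receptor FGFR1 was at -2.52 and -1.01 and RORA, a nuclear receptor of T helper cells, at -1.35 and -1.07 in the authors' deposited tables (combined adjusted p = 0.000469 and 0.00669).

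Non-polyadenylated RNAs were higher in shPRKCQ cells in DMSO. Besides RN7SK, the 6 such RNAs tested there were all positive, with a median log2 fold change of 1.78: SNORD3A, the highest, at 3.998, RN7SL1 at 2.40, SNORD17 at 1.80, RN7SL2 at 1.76, MT-RNR1 at 1.72 and MT-RNR2 at 0.72 in the authors' deposited table. In TPA the same 6 had a median of 0.0042 (bootstrap 95% interval -0.17 to 0.18) although PRKCQ was as low there, which argues against an effect of the knockdown common to both treatments. Replication-dependent histone genes, classed here by symbol as lacking a poly(A) tail, were positive for 17 of 21 in DMSO (median 0.42). Whether each of them lacks a tail was not checked. Both classes lay above random sets there (one-sided permutation p = 0.0001, the smallest that 10000 draws can give). The 51 histone genes tested in TPA, a larger set, did so too (median 0.14, permutation p = 0.0087). The 46 non-polyadenylated RNAs besides RN7SK tested in TPA did not (median 0.048, permutation p = 0.2421). A rise of histone genes alone therefore does not mark carry-over. The random sets and the bootstrap take genes as independent, so their values do not cover the spread between libraries. RNAs that move together in 1 library could give such values. The DMSO values are what carry-over of such RNA into some shPRKCQ libraries in poly(A) selection would give, and that remains a candidate explanation. An effect of the knockdown only in vehicle stays open, since values per library were not analysed here.

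For the genes changed in both treatments, a hairpin acting on other transcripts through its seed was set against loss of PRKCQ. Of 16384 words of 7 bases, 4 marked 3' UTRs of genes lower in shPRKCQ cells past a Bonferroni bound in both tables and 0 marked higher genes in both; 3 of the 4 occur in PRKCQ transcripts, as 17.2% of all words do, which chance gives at 0.0178 for at least 3 of 4 (a count looked at afterwards, over words that overlap) and at 0.531 for at least 1, the criterion set beforehand. The lowest-scoring, ATTCCAA (-7.80 in DMSO and -6.40 in TPA; median log2 fold change of -0.0081 with it and 0.014 without in DMSO), occurs in PRKCQ in coding sequence, within ATTCCAAA at chromosome 10, 6462317 to 6462324, and in the last exon outside the coding sequence at 6427251 to 6427257 (GRCh38, minus strand, exons 14 and 18 of 18 in ENST00000263125.9). The word is carried by 36.0% of the 89 genes lower in the combined test, against 18.3% at matched UTR length, and by 13.6% of the 44 higher, which is no independent test because the word was picked on the same values; of the 4 shared calls besides PRKCQ, 2 carry it (EAF1 and LDLRAD3), against 22.3% (permutation p = 0.2135), too few genes to decide, and seed-matched repression stays a candidate explanation for part of the falls, while with 1 shPRKCQ label and the hairpin sequence not used here, loss of PRKCQ and a change in a cellular microRNA stay open too. A regional gain or loss of DNA around all 5 shared calls at once is argued against. Their neighbours within 1 Mb had a mean signed z of -0.015 in DMSO (random sets -0.34 to 0.31, permutation p = 0.475). A shift of 1 planted around all 5 genes was recovered in 100% of simulations. Those simulations drew genes as independent, whereas adjacent genes correlated genome-wide (r = 0.109 in DMSO and 0.129 in TPA). A change around a single gene, or one smaller than the window, was not simulated and could be missed.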
